A study of Mus musculus with 27 samples.

How the data were processed

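Polyadenylated RNA of mouse primary cortical cells was measured in 27 libraries, with 3 in each of 9 groups. Under DRB the groups were unstimulated, bicuculline and BDNF, and under triptolide unstimulated and bicuculline, each as whole cell, nucleus and cytosol. Libraries were made from total RNA with a stranded mRNA kit (TruSeq), as the sample descriptions state. The values are FPKM computed by the authors, and the deposited table holds 1 value per gene and library on the gene models of FASTDB, a database of transcript annotations, on mm10. The submitters' processing notes name FastQC, Picard, SAMtools, STAR 2.4.0 and mm10. The counting program, its strand setting and its handling of reads that map to several places are not given in the sources used here. This leaves the levels of ribosomal protein genes, which have many pseudogenes, less certain than others.

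The table has 59489 entries, of which 23508 have a gene symbol, 35981 have none and 12156 are 0 in every library. An entry named A // B merges neighbouring genes, and the mitochondrially encoded RNAs were named by their position. Low values of a gene lie on steps, and the steps of 772 single-exon genes gave the depth of each library, 67618801 to 148029426 fragments. In these genes 100% of 6599 low values lay within 0.02 fragment of a step of whole or 0.5 fragments. The genes were chosen for values on even steps, and the depth was set from them, so this share was fixed in advance. At that depth 10 fragments on a transcript of 2 kb make an FPKM of 0.0338 to 0.0739. Whether the counts behind the values are whole or fractional is not settled by the steps. Whole read counts were not recovered and no count-based test was run. GENCODE M21 gave gene biotype, introns and overlaps, and 11853 of the 14641 entries with an FPKM of at least 1 in 3 libraries matched it.

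Values were used as deposited, as log2(FPKM + 0.5). Genes with an FPKM of at least 1 in at least 3 libraries of the experiment were tested, which left 13321 under DRB, 14205 under triptolide and 13814 for the comparison of both. limma 3.58.1 in R 4.3.3 fitted a mean per group with variance moderation (trend and robust), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. There were 10 comparisons. They were bicuculline and BDNF each against unstimulated cells under DRB, BDNF against bicuculline, the bicuculline response in each RNA fraction under triptolide, its difference between nucleus and cytosol, nucleus against cytosol in each state, and the difference of the bicuculline response between DRB and whole cells under triptolide. The overlap of the responses under DRB was set against 100 simulations of unchanged groups with shared controls, drawn with the spread of independent libraries, and against 100 drawn with the spread within cultures. On simulated data with 100 changed genes of each size, a log2 change of 1 was recovered for 85% of genes in the DRB response, 96% in the nuclear response, 90% in the difference between nucleus and cytosol and 61% in that between DRB and triptolide. For a log2 change of 0.5 the shares were 49%, 64%, 39% and 20%, and 2.41 to 5.84% of calls were false. The simulated genes and libraries were independent, without differences between cultures, so these shares need not hold for the real libraries. Figures and summaries used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

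The groups, comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Of 20 lists, 1 is not reported here, and neither are single members of others, while counts of lists cover all 20. The rest were immediate early genes, delayed activity genes, ERK feedback, glutamatergic synapse, GABAergic synapse, voltage-gated channels, CLK kinases and SR proteins, spliceosome and hnRNPs, nuclear long noncoding RNAs, hosts of small nucleolar RNAs, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded RNAs, and markers of excitatory neurons, astrocytes, oligodendrocytes, microglia, progenitors and proliferation, and vascular and mesenchymal cells. A list was tested with camera (preset correlation 0.01) where at least 5 members were tested, and again with an estimated correlation and with fry. The vascular list had too few tested members in both experiments, and the microglia list under DRB. No entry carries the name of 14 of the listed genes (Malat1, Neat1, Kcnq1ot1, Snhg14, Jun, Junb, Jund, Sox2, Snhg8, Snhg16, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8), so these are missing from the lists. Apart from mitochondrial ones, entries without a symbol were not assigned to genes by position. Some of these genes may therefore be among the gene models without a symbol, which were tested. The named genes of a comparison are the 6 largest rises and the 6 largest falls among called genes with a mean FPKM of at least 5 in the groups compared, a symbol that is not a provisional one, and every library of one group above every library of the other (chance separates 10% of genes so with 3 against 3), a condition not set for differences between responses. Where fewer were called, all are named, and where none was called, the 5 smallest p are given as values. To these come up to 3 called members of each list, and Fos, Arc, Npas4, Egr1, Nr4a1, Bdnf, Clk1, Clk4, Malat1 and Meg3.

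Whether the replicate numbers pair the libraries was checked from the residuals from the group means. Libraries of the same number correlated at 0.463 to 0.902 under DRB (median 0.780, 9 pairs) and at 0.256 to 0.692 under triptolide (median 0.523, 45 pairs), against medians of -0.532 and -0.245 for different numbers, and the culture names in the sample descriptions tie the same libraries together. The fit without a block was kept as planned. The fit with replicate number as a block is given beside results whose call it changes or whose count it moves by more than 1.5 times. List calls that the block gained with the preset correlation, 16 in all, are an exception. Of these only that of glutamatergic synapse genes in unstimulated cells is given.

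The alternatives fixed beforehand were a pseudocount of 0.1 or 1 FPKM, no filter or a mean FPKM of at least 5, scaling by the median ratio to a geometric mean library, quantile normalization, variance moderation without trend and not robust, only the groups compared in the fit, the replicate block, and leaving out each library in turn. Quantile normalization gives the same value to rows of the same rank. The mitochondrially encoded RNAs are among the highest values of a library. Their medians at or near 0 with quantile normalization therefore largely follow from the method and do not test their shift. The replicate block together with median-ratio scaling, and the fits without bicuculline nuclei 1 and 3, were added after the data were seen. Other splits of the libraries were counted for each comparison, with all 10 for 3 against 3 and 100 drawn for the differences between responses. Intron retention is not analysed here, since the values are per gene, and no raw reads were used here.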

Results

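Polyadenylated RNA of mouse primary cortical cells (embryonic day 16.5, kept 14 days in culture) was sequenced in 27 libraries, in 9 groups of 3. In the first experiment (9 libraries) transcription was inhibited with DRB, a blocker of transcription elongation (50 µM, 2 h). The cells were left unstimulated, given bicuculline (20 µM, 1 h), which blocks GABA-A receptors and so raises neuronal activity, or given the growth factor BDNF (50 ng/mL, 1 h), the ligand of the receptor TrkB. In the second experiment (18 libraries) transcription was inhibited with triptolide, a blocker of transcription initiation (1 µM, 3 h), with or without bicuculline, and RNA was taken from whole cells, nuclei or cytosol. The series title and design text place the study's question in how each stimulus remodels the neuronal transcriptome through retained introns. The deposited table gives 1 FPKM value per gene and library, so intron retention is not analysed here and the comparisons are of gene levels. The libraries held 83456703 to 148029426 fragments under DRB and 67618801 to 89491743 under triptolide, as estimated from the steps between low values. Genes with an FPKM of at least 1 numbered 12812 to 13039 per library under DRB and 12056 to 13911 under triptolide. Mitochondrially encoded RNAs held 4.73 to 5.96% of all FPKM under DRB and 8.72 to 12.5% under triptolide. On the first principal component (51.5% of the variance) of the DRB libraries, those of replicate number 2 lay apart from the others. The first component of the triptolide libraries (70.1%) followed the RNA fraction. Coordinates below are of mm10, errors of FPKM values are SD over the 3 libraries of a group, and errors of log2 changes are SE. Replicates are the libraries numbered 1 to 3 in each group. The p-values of the fit without a block measure the spread between these libraries, differences between cultures included. Those differences cancel in changes within a culture, which the fit with replicate number as a block uses.

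Under DRB, bicuculline raised the mRNAs of activity-regulated genes. Npas4 (chromosome 19, 4984354 to 4990316), a transcription factor induced by neuronal activity, went from 5.87 ± 2.81 to 162 ± 35.2 FPKM, a 26.8-fold rise with 0.5 FPKM added to each value. Arc (chromosome 15, 74669081 to 74672572), whose protein acts at synapses, went from 0.924 ± 0.0701 to 29.7 ± 2.0 FPKM, and Fos (chromosome 12, 85473889 to 85477273), a subunit of the transcription factor AP-1, from 11.8 ± 4.81 to 144 ± 3.04 FPKM. The log2 changes were 4.74 ± 0.30 for Npas4 (adjusted p = 1.5e-04), 4.40 ± 0.12 for Arc (adjusted p = 1.09e-06) and 3.64 ± 0.24 for Fos (adjusted p = 1.77e-04), higher in 3 of 3 bicuculline libraries than in every unstimulated one. Other large rises were those of Fosb (log2 change 4.04), an AP-1 subunit, of the stress-response genes Gadd45g (3.08) and Gadd45b (2.56), and of the transcription factors Nr4a1 (2.21) and Egr1 (1.47). Of the immediate early genes, those switched on first after a stimulus, 20 of 27 rose (23 adjusted over the list alone), with a median log2 change of 1.55 (camera adjusted p = 1.13e-126, and adjusted p = 7.11e-04 with an estimated correlation). Of 20 genes of ERK feedback, which dampen signalling through the kinase ERK, 2 rose (5 adjusted over the list alone), namely Errfi1 (1.14) and Dusp6 (0.90), with a list median of 0.09 (adjusted p = 8.77e-08, and adjusted p = 0.0493 with an estimated correlation, which became 0.139 with replicate number as a block). Of 24 delayed activity genes, which follow the immediate early genes, 2 rose, Tiparp (1.56) and Plk2 (1.08), and the list test gave an adjusted p = 1.05e-07 and an adjusted p = 0.112 with an estimated correlation. The lists of astrocyte markers (median -0.11), glutamatergic synapse genes (-0.05), voltage-gated channels (-0.06) and oligodendrocyte markers (-0.22) lay lower than other genes, with no member called by limma or at an unadjusted p under 0.05 (0 genes), and with adjusted p = 0.112, 0.679, 0.955 and 0.679 with an estimated correlation. Bdnf (0.42), Clk1 (0.16), Clk4 (0.02) and Meg3 (-0.30) did not pass the test. In all, limma called 41 of 13321 genes, 41 higher and 0 lower, at 266 genes with an unadjusted p under 0.05 (238 higher, 28 lower), and 31 of the 41 had a log2 change of at least 1 in size. With replicate number as a block 76 genes were called, 76 higher and 0 lower, and all 41 stayed among them. Without unstimulated library 1 the count was 27, as it was without unstimulated library 3, and the call of Nr4a1 was lost without any one of bicuculline libraries 1, 2 and 3 or unstimulated libraries 1 and 3 (highest adjusted p = 0.0746).

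BDNF under DRB raised a larger number of genes. Arc went from 0.924 ± 0.0701 to 124 ± 23.1 FPKM, 86.5-fold with 0.5 FPKM added (log2 change 6.44 ± 0.12, adjusted p = 4.1e-08). Fos reached 180 ± 18.9 FPKM (log2 change 3.95 ± 0.24), Npas4 74.5 ± 15.4 FPKM (3.63 ± 0.30), and the zinc finger transcription factor Egr1 rose from 22.2 ± 3.18 to 205 ± 30.6 FPKM (3.18 ± 0.13). Egr4, of the same family, rose from 4.50 ± 1.26 to 71.4 ± 4.92 FPKM, and the immediate early gene Ier2 from 1.01 ± 0.167 to 15.2 ± 2.26 FPKM. Of the immediate early genes 21 of 27 rose (26 adjusted over the list alone), with a median log2 change of 2.17 (camera adjusted p = 2.79e-135, and adjusted p = 5.85e-04 with an estimated correlation). Of 20 ERK feedback genes 4 rose (4 adjusted over the list alone), among them Errfi1 (1.52), the phosphatase gene Dusp5 (1.46) and Dusp6 (0.57). That list's adjusted p was 1e-10, and its adjusted p = 0.0218 with an estimated correlation became 0.0648 with replicate number as a block. Of 24 delayed activity genes 2 rose (7 adjusted over the list alone), Tiparp (1.66) and Plk3 (0.79), with a list adjusted p = 9.96e-10 and adjusted p = 0.0900 with an estimated correlation. Astrocyte markers, mitochondrially encoded RNAs and nuclear-encoded genes of oxidative phosphorylation lay lower than other genes with the preset correlation (medians -0.10, -0.15, which became -0.03 with quantile normalization, and -0.04), with no member called by limma or at an unadjusted p under 0.05 (0 genes), and adjusted p = 0.0989, 0.395 and 0.892 with an estimated correlation. With median-ratio scaling the mitochondrially encoded median was -0.16. Fosb (4.20) and Nr4a1 (2.30) rose, and Bdnf (0.30), Clk1 (0.26), Clk4 (0.10) and Meg3 (-0.06) did not pass the test. Over all genes limma called 85 of 13321 genes, 85 higher and 0 lower, at 462 genes with an unadjusted p under 0.05 (445 higher, 17 lower). With replicate number as a block 199 genes were called (194 higher, 5 lower), with all 85 among them. The count was 52 without BDNF library 3, 54 without unstimulated library 3 and 56 without unstimulated library 1. The call of Plk3 was lost without BDNF library 2 or 3 or unstimulated library 1 or 3, and that of Dusp6 without any BDNF library or unstimulated library 2 or 3.

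Between the stimuli, BDNF gave higher levels of several immediate early genes than bicuculline did. Arc was at 124 FPKM after BDNF and 29.7 after bicuculline (log2 difference 2.03 ± 0.12, adjusted p = 8.29e-04). Ier2 (1.87 ± 0.13), Egr1 (1.71 ± 0.13), Egr2 (1.62 ± 0.12), Egr4 (1.61 ± 0.15) and the antiproliferative gene Btg2 (1.29 ± 0.15) were higher after BDNF too. Plk2, a kinase gene induced by activity, was lower after BDNF, at 21.9 ± 1.23 FPKM against 36.4 ± 2.54 (-0.72 ± 0.07). Npas4 was at 74.5 FPKM after BDNF and 162 after bicuculline, a log2 difference of -1.12 that did not pass the test (adjusted p = 0.700) and did with replicate number as a block (adjusted p = 0.0137). Among the immediate early genes 7 of 27 were higher and 1 was lower after BDNF (10 and 5 adjusted over the list alone), with a median log2 difference of 0.16 (camera adjusted p = 1.17e-06, and adjusted p = 0.794 with an estimated correlation). With the preset correlation, glutamatergic synapse genes and voltage-gated channels lay higher after BDNF and mitochondrially encoded RNAs and oxidative phosphorylation genes lower, and each had an adjusted p = 0.794 with an estimated correlation. Members of these 4 lists were called by limma in 0 cases, against 0, 1, 2 and 0 with an unadjusted p under 0.05. Fos (0.31), Nr4a1 (0.09), Bdnf (-0.12), Clk1 (0.10), Clk4 (0.09) and Meg3 (0.23) did not differ past the threshold. In all, limma called 17 genes, 15 higher and 2 lower after BDNF, at 347 genes with an unadjusted p under 0.05 (271 higher, 76 lower). The second lower gene, Trib1 (-0.91), was chosen for naming after its values were seen. With replicate number as a block 72 genes were called (60 higher, 12 lower), with all 17 among them. Leaving out BDNF library 1, BDNF library 3 or bicuculline library 1 gave 9 calls each. The calls of Arc, Ier2, Egr1, Egr2, Egr4 and Plk2 held without each of the 6 libraries in turn, and that of Btg2 was lost in 3 of the 6 fits.

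The genes raised by both stimuli numbered 35, against 0.262 if the calls were independent, and 0 were called lower in both. The stimulated groups were compared with the same 3 unstimulated libraries, which gives chance overlap. In 100 simulations of unchanged groups against shared controls the overlap was 0 on average and at most 0. With no gene changed hardly any is called, so an overlap near 0 follows from the setting. It cannot show how much the shared controls add beside real changes. The changes correlated across genes at r = 0.709, or 0.433 without the called genes, against 0.499 in those simulations, and their covariance was 0.0204 against 0.0144, a difference of 0.00602 (genes are not independent replicates). Those simulations took libraries as independent, and with the smaller spread within cultures, since the replicate numbers pair the libraries, the covariance was 0.00349 (a difference of 0.0169), the correlation 0.50 and the overlap at most 1. The 3 controls cannot be divided so that each stimulus has at least 2 of its own, and part of the excess over independent calls may come from the shared controls. With replicate number as a block 59 genes were called with both stimuli.

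**Figure D1:**
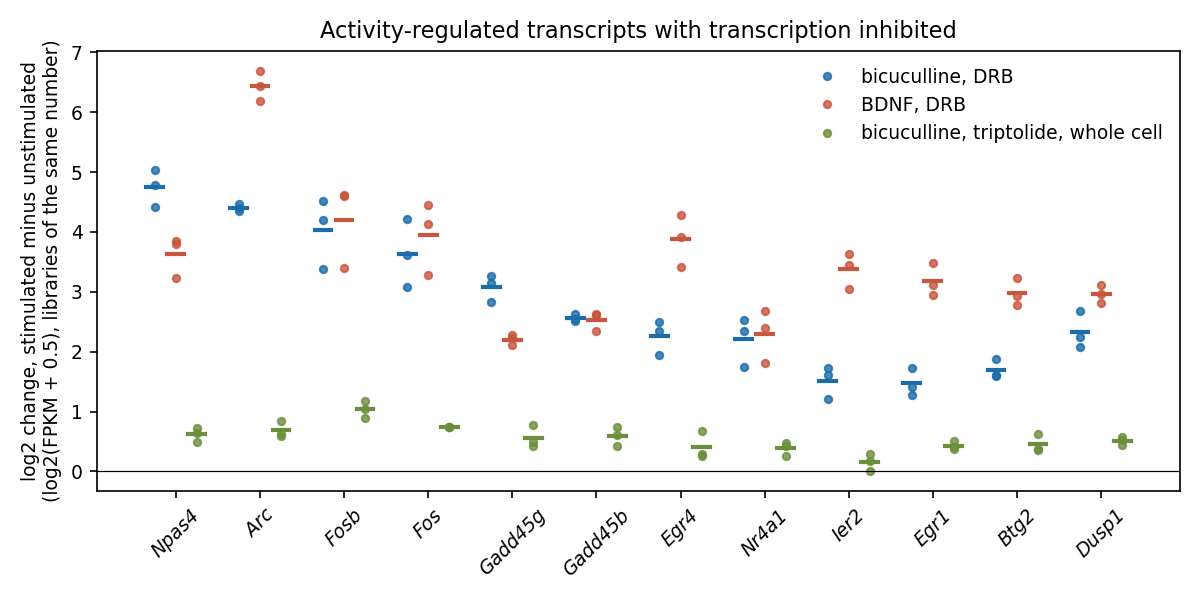
Log2 change (vertical axis) of 12 activity-regulated genes with bicuculline and with BDNF under DRB, and with bicuculline in whole cells under triptolide, each point being a stimulated library minus the unstimulated library of the same number and each bar the mean of 3. The mean change of Arc was 4.40 with bicuculline and 6.44 with BDNF under DRB, against 0.69 with bicuculline under triptolide.

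In whole cells under triptolide, the number of genes past the threshold after bicuculline depended on the pairing. It was 5 in the fit without a block and 601 with replicate number as a block. Fos went from 3.03 ± 0.678 to 5.42 ± 1.15 FPKM (log2 change 0.75 ± 0.20), Arc from 1.47 ± 0.477 to 2.73 ± 1.08 (0.69 ± 0.36) and Npas4 from 1.37 ± 0.267 to 2.4 ± 0.624 (0.62 ± 0.23). These changes did not pass the test (adjusted p = 0.157, 0.528 and 0.305), and with replicate number as a block they did (adjusted p = 4.69e-06, 6.4e-04 and 8.57e-04), as did Egr1 (0.43, blocked adjusted p = 0.00310) and Nr4a1 (0.39, blocked adjusted p = 0.0115). Of 20 immediate early genes tested 1 rose (13 adjusted over the list alone, 14 with the block), with a median log2 change of 0.42 (camera adjusted p = 1.43e-11, and adjusted p = 0.463 with an estimated correlation, which became 0.00461 with the block). Ribosomal protein genes (median -0.09), mitochondrially encoded RNAs (-0.26), astrocyte markers (-0.12), genes hosting small nucleolar RNAs (-0.15) and oxidative phosphorylation genes (-0.03) lay lower than other genes, and voltage-gated channels (0.08) and spliceosome genes (0.05) higher. None of their members was called by limma, and at an unadjusted p under 0.05 4, 3, 0, 3 and 2 members were lower and 6 and 13 higher, in that order. For these lists the adjusted p ran from 0.463 to 0.606 with an estimated correlation. The median of the mitochondrially encoded RNAs was -0.30 with median-ratio scaling. It became -0.03 with quantile normalization, which by its method evens out the highest values. That of the spliceosome genes became 0.01 with median-ratio scaling. Across the transcriptome limma called 5 of 14205 genes (2 higher, 3 lower), at 1566 genes with an unadjusted p under 0.05 (1262 higher, 304 lower). The called genes were Fosb (1.04 ± 0.17, from 0.424 to 1.41 FPKM) and 4 gene models without a symbol (log2 changes 0.96, -1.50, -1.01 and -0.88 for models GSMG0007926, GSMG0002765, GSMG0018786 and GSMG0039764). The models were chosen for naming after their values were seen. With the block 601 genes were called (528 higher, 73 lower), with all 5 among them, and 330 (255 higher, 75 lower) with the block and median-ratio scaling. Without 1 library the count was 2 (bicuculline 1 or unstimulated 2), 3 (bicuculline 2) or 1 (bicuculline 3 or unstimulated 3). The call of Fosb was lost in 5 of the 6 such fits, and that of GSMG0002765 in 0.

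The bicuculline response of the activity-regulated genes was larger under DRB than in whole cells under triptolide. The log2 response of Npas4 was larger by 4.12 ± 0.39 (adjusted p = 8.58e-04), that of Arc by 3.72 ± 0.31 (adjusted p = 5.2e-04), that of Fosb by 3.0 ± 0.38 and that of Fos by 2.89 ± 0.35. Gadd45g (2.52), Egr4 (1.85) and Tiparp (1.42) differed likewise. Of 27 immediate early genes 13 had a larger response under DRB (21 adjusted over the list alone), with a median difference of 1.24 (camera adjusted p = 3.3e-81, and adjusted p = 0.00183 with an estimated correlation). A further 9 lists passed the list test with the preset correlation, and had an adjusted p of 0.266 to 0.588 with an estimated one. Among these, delayed activity genes had a median of -0.00 and a mean of 0.13 with a positive test, their median being 0.03 with median-ratio scaling, and the median of mitochondrially encoded RNAs (0.28) was 0.00 with quantile normalization. The spliceosome list (adjusted p = 0.0467) did not pass with replicate number as a block (adjusted p = 0.0510). Nr4a1 (1.82) and Egr1 (1.04) did not pass the test, and did with replicate number as a block (adjusted p = 0.00314 and 0.00228). Bdnf (0.35), Clk1 (0.29), Clk4 (0.24) and Meg3 (-0.14) did not pass it either way. Across 12909 genes the responses correlated at r = 0.299, and 27 of the 28 genes called under DRB and tested in both had the same sign under triptolide, with median log2 changes of 1.35 and 0.395. In all, limma called 19 of 13814 genes, 19 with a larger response under DRB and 0 with a smaller one, at 310 genes with an unadjusted p under 0.05 (122 larger, 188 smaller). With the block 38 genes were called (36 higher, 2 lower), with all 19 among them. Without triptolide bicuculline library 2 the count was 12, as it was without triptolide unstimulated library 1, and the calls of Egr4 and Tiparp were each lost in 1 of the 12 fits that left out a library. The experiments differ in inhibitor, its duration and the cultures, which cannot be told apart, and the titles of the DRB libraries state no RNA fraction.

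Nuclear and cytosolic RNA of unstimulated cells differed for most genes. Xist (chromosome X, 103460373 to 103483233), the noncoding RNA that coats the inactive X chromosome, was at 307 ± 229 FPKM in nuclei and 2.20 ± 1.87 in cytosol. The noncoding RNAs Firre (log2 ratio 3.80 ± 0.17), Mirg (3.46 ± 0.21) and Meg3 (3.33 ± 0.25) were nuclear as well. Among coding genes, the kinase gene Clk1 (chromosome 1, 58410190 to 58424088), whose protein phosphorylates splicing factors, was at 23.6 ± 3.28 FPKM in nuclei and 1.41 ± 0.281 in cytosol (3.66 ± 0.18), and the cyclin gene Ccnl2 (3.90 ± 0.18), Leng8 (3.93 ± 0.24) and Clk4 (2.73 ± 0.13) were also higher in nuclei. In cytosol the neuropeptide genes Sst (234 ± 18.9 FPKM against 71.3 ± 4.44 in nuclei, log2 ratio -1.70 ± 0.11) and Npy (-1.44 ± 0.16) were higher, with Crhbp (-1.74 ± 0.23), Nxph1 (-1.45 ± 0.08) and Slc32a1 (-1.46 ± 0.10), the vesicular transporter of GABA. Of the genes of CLK kinases and SR proteins, which act in splicing, 32 of 38 were higher in nuclei and 4 lower (median log2 ratio 1.11, camera adjusted p = 1.7e-06, and adjusted p = 0.610 with an estimated correlation), among them Rsrp1 (2.89). Of 14 nuclear long noncoding RNAs 9 were higher and 2 lower (median 1.63, adjusted p = 0.0292, and adjusted p = 0.610 with an estimated correlation). Of 28 GABAergic synapse genes 1 was higher and 22 were lower in nuclei (median -0.72, adjusted p = 2.21e-08, and adjusted p = 0.168 with an estimated correlation). Voltage-gated channels (11 higher and 25 lower of 53, with Kcnc2 at -1.30) and delayed activity genes (3 and 12 of 23, with Vgf at -1.10) also lay lower in nuclei, with adjusted p = 0.00557 and 0.0283, and adjusted p = 0.605 and 0.791 with an estimated correlation.

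The following lists did not pass the list test in unstimulated cells, except that glutamatergic synapse genes (adjusted p = 0.0535) did with replicate number as a block (adjusted p = 0.0472). Their members higher and lower in nuclei were 15 and 22 of 48 glutamatergic synapse genes (Camk2a, a synaptic kinase gene, at 1.27), 21 and 25 of 60 spliceosome and hnRNP genes (Prpf39 at 2.89, Snrnp70 at 2.56), 10 and 20 of 46 oxidative phosphorylation genes, 6 and 2 of 76 ribosomal protein genes, 9 and 2 of 16 ERK feedback genes, 6 and 2 of 20 immediate early genes, and 6 and 1 of 14 genes hosting small nucleolar RNAs (Snhg20 at 3.17). For cell type markers they were 6 and 0 of 14 for astrocytes, 4 and 6 of 14 for excitatory neurons, 1 and 3 of 12 for oligodendrocytes, 5 and 2 of 14 for progenitors and proliferation (Nes at 1.85), 0 and 0 of 9 for microglia, and for mitochondrially encoded RNAs 1 and 2 of 7. Of the vascular and mesenchymal markers 4 were tested, too few for a list test. Quantile normalization moved the median ratio over all genes from 0.0585 to -0.124, and with it the medians of the ERK feedback, immediate early, microglia, progenitor, oxidative phosphorylation, ribosomal protein and spliceosome lists changed sign. Bdnf was lower in nuclei (-0.64 ± 0.19) and Npas4 higher (1.00 ± 0.23). Fos (-0.35), Nr4a1 (0.45) and Arc (0.30) passed the test with replicate number as a block (adjusted p = 2.24e-05, 3.57e-05 and 0.00377) and not without it, and Egr1 (-0.04) passed neither. In all, limma called 9511 of 14205 genes, 5540 higher and 3971 lower in nuclei, and 9507 of them were called with the block as well. Of 62 named calls 57 held without each of the 6 libraries in turn, and those of Gfap, Aldh1l1, Rpl3, mt-Nd2 and mt-Nd3 did not. The values are shares of each fraction's own RNA, so a ratio is relative to other genes and not an amount per cell. Of the exonic length of Slc32a1, 24.9% overlaps a gene on the opposite strand, and for Xist 11%.

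After bicuculline the fractions differed in much the same way, with log2 ratios that correlated with those of unstimulated cells at r = 0.953 across genes. Xist (6.88 ± 1.07), Ccnl2 (3.47 ± 0.18), Leng8 (3.11 ± 0.24), Meg3 (3.08 ± 0.25) and Clk1 (2.97 ± 0.18) were higher in nuclei. Sst (-1.81 ± 0.11), Crhbp (-1.56 ± 0.23), Npy (-1.53 ± 0.16) and Kcnc2 (-1.28 ± 0.12) were higher in cytosol. CLK and SR genes were higher for 30 of 38 members and lower for 5, nuclear long noncoding RNAs for 9 and 3 of 14, GABAergic synapse genes for 0 and 23 of 28, and oxidative phosphorylation genes for 6 and 26 of 46. Of the ribosomal protein genes 0 were higher and 52 of 76 lower (median -0.26, or -0.10 with quantile normalization). These 5 lists passed the list test (adjusted p = 2.47e-06, 0.0156, 2.47e-06, 0.0292 and 2.47e-06 in the order given), and with an estimated correlation their adjusted p was 0.791, 0.791, 0.416, 0.955 and 0.928. The median of the oxidative phosphorylation genes (-0.17) was positive with quantile normalization (0.04), and with replicate number as a block their list did not pass (adjusted p = 0.0549). Fos (-0.28), Arc (0.36) and Npas4 (0.27) passed the test with the block (adjusted p = 2.19e-04, 0.00113 and 0.00596) and not without it, Egr1 (-0.14), Nr4a1 (0.16) and Bdnf (-0.19) passed neither, and Clk4 (2.04) passed both. Across the transcriptome limma called 8983 of 14205 genes, 4449 higher and 4534 lower in nuclei, and 8980 of them were called with replicate number as a block as well. Of 59 named calls 55 held without each of the 6 libraries in turn.

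**Figure D2:**
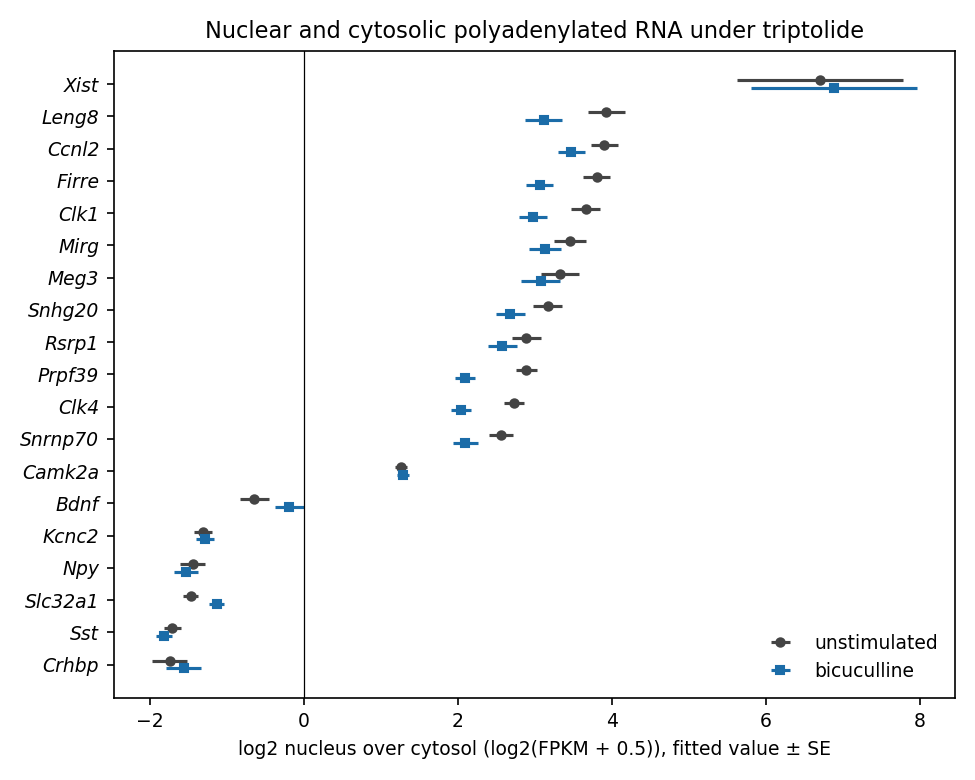
Log2 ratio of nuclear to cytosolic RNA under triptolide (horizontal axis) of 19 genes named in the text, in unstimulated cells (circles) and after bicuculline (squares), as fitted values with SE from 3 libraries per group. Points right of 0 are higher in nuclei, from 1.27 for Camk2a to 6.70 for Xist in unstimulated cells, and the points of Crhbp and Sst lie lowest in both states.

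In nuclei under triptolide, genes called higher after bicuculline included genes of synapses and ion channels, and genes called lower included genes of ribosomal proteins. Reln (chromosome 5, 21884454 to 22344706), which encodes the secreted glycoprotein reelin, went from 14.5 ± 1.09 to 23.6 ± 0.893 FPKM (log2 change 0.68 ± 0.07, adjusted p = 3.63e-04). Hapln1 (0.63 ± 0.12), a link protein gene of the extracellular matrix, Rtn4r (0.59 ± 0.08), the Nogo receptor gene, Nwd2 (0.52 ± 0.12), Lrp12 (0.50 ± 0.06) and Wscd2 (0.45 ± 0.09) rose as well. The largest falls among the named genes were those of Whamm, from 7.44 ± 1.20 to 4.11 ± 0.157 FPKM (-0.77 ± 0.11), Mir6236 (-0.58 ± 0.13), Micalcl (-0.58 ± 0.11), Rock1 (-0.57 ± 0.10), Tmsb10 (-0.48 ± 0.11), which encodes an actin-binding thymosin, and Zscan26 (-0.47 ± 0.09). Of 48 glutamatergic synapse genes 6 rose (13 adjusted over the list alone, 17 with replicate number as a block), among them Gria3 (0.39), Grm7 (0.36) and Nrxn3 (0.34), with a list median of 0.13 (camera adjusted p = 1.35e-08, and adjusted p = 0.0423 with an estimated correlation, which became 0.0579 with the block). Of 76 ribosomal protein genes 9 fell (49 adjusted over the list alone, 56 with the block), among them Rpl12 (-0.43), Rps20 (-0.38) and Rplp1 (-0.35), with a list median of -0.26 (adjusted p = 1.09e-24, and adjusted p = 0.195 with an estimated correlation). Of 53 voltage-gated channel genes 3 rose (11 adjusted over the list alone), among them Kcnh7 (0.43) and Hcn4 (0.41), and of 28 GABAergic synapse genes 1 rose (6 up and 1 down adjusted over the list alone), the chloride transporter gene Slc12a5 (0.33). Their list medians were 0.10 and 0.15 (adjusted p = 1.02e-06 and 5e-06, and adjusted p = 0.0746 and 0.189 with an estimated correlation). Of 20 immediate early genes 4 rose (7 adjusted over the list alone, 13 with the block), among them Fosb (1.18), Cyr61 (0.90) and Fosl2 (0.39), with a list median of 0.38 (adjusted p = 8.84e-09, and adjusted p = 0.241 with an estimated correlation, which became 0.0198 with the block).

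Other lists moved in nuclei with the preset correlation only. Delayed activity genes lay higher (median 0.24), and astrocyte markers (-0.17), CLK and SR genes (-0.09, with Srsf7 called at -0.37), mitochondrially encoded RNAs (-0.17, and 0.00 with quantile normalization), oxidative phosphorylation genes (-0.10, with Ndufa5 called at -0.22) and genes hosting small nucleolar RNAs (-0.18) lower, with an adjusted p of 0.454 to 0.714 with an estimated correlation. With median-ratio scaling the mitochondrially encoded median in nuclei stayed at -0.17. Fos (0.73), Arc (0.69), Egr1 (0.38) and Bdnf (0.30) passed the test with replicate number as a block (adjusted p = 1.49e-06, 2.41e-04, 0.00175 and 0.0460) and not without it. Npas4 (0.11), Nr4a1 (0.13), Clk1 (-0.23), Clk4 (-0.23) and Meg3 (-0.03) passed neither. Over all genes limma called 257 of 14205 genes, 140 higher and 117 lower, at 2467 genes with an unadjusted p under 0.05, and with the block 1862 (1096 higher, 766 lower), with all 257 among them. Leaving out single libraries ended many calls and added others. Without bicuculline nuclei 1, 2 or 3 the counts were 52, 524 and 53, and without unstimulated nuclei 1 or 3 they were 21 and 51. Of 27 named calls 5 (Reln, Rtn4r, Lrp12, Whamm and Fosb) held in each such fit, and 17, 5, 21, 22, 9 and 17 were lost without bicuculline 1, 2 and 3 and unstimulated 1, 2 and 3. With only the 6 nuclear libraries in the fit 1 gene was called. The nuclear libraries also differed in how nuclear their RNA was. Coding genes with a log2 ratio of nucleus to cytosol over 1 in the other cultures were set against those under 0. Their difference in nuclear change was -0.334, 0.115 and -0.421 in cultures 1, 2 and 3. The glutamatergic, GABAergic and channel lists had medians under 0 for that ratio in unstimulated cells (-0.24, -0.72 and -0.22). Cytosol carried over into bicuculline nuclei is therefore not set apart from the rise of these lists. On a scale from the mean of the unstimulated cytosols (0) to that of the unstimulated nuclei (1) of the other cultures, bicuculline nuclei lay at 0.869 ± 0.106 and unstimulated nuclei at 0.982 ± 0.0388 (SD, n = 3 each, 2-sided exact permutation test p = 0.3, where 0.1 is the smallest possible). Without bicuculline nuclei 1 and 3, which lay lowest, 14 genes were called (3 higher, 11 lower), a fit chosen after the data were seen, in which the lone library is assumed to vary like the other groups.

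**Figure D3:**
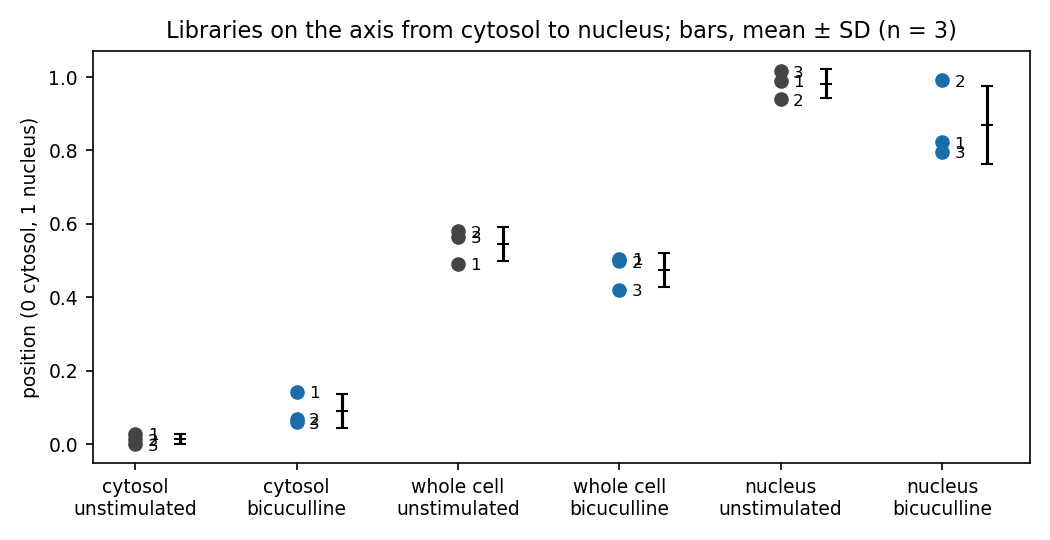
Position of each triptolide library on a scale from unstimulated cytosol (0) to unstimulated nuclei (1), computed from the unstimulated libraries of the other cultures, each point being a library, with means of 0.869 for bicuculline and 0.982 for unstimulated nuclei and 0.0909 and 0.0141 for the cytosols. Bicuculline nuclei 1 and 3 lie below every unstimulated nucleus and bicuculline nuclei 2 (0.991) among them.

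In cytosol under triptolide, 213 of 2584 coding genes with more than 15 introns (8.24%) were called higher after bicuculline. Among coding genes with 0 introns 1 of 145 was (0.690%), and the number of calls depended on the scaling, as given below. Pnisr (chromosome 4, 21847583 to 21876475), a gene of an SR-related protein, went from 12.5 ± 1.63 to 20.3 ± 2.60 FPKM (log2 change 0.68 ± 0.15, adjusted p = 0.0282), and Htt, the huntingtin gene, from 4.91 ± 0.532 to 7.97 ± 1.26 FPKM (0.64 ± 0.14). Smg1 (0.60 ± 0.14), a kinase gene of nonsense-mediated decay, Tnrc6a (0.60 ± 0.10), of microRNA silencing, Ddx26b (0.60 ± 0.11) and the transporter gene Abcc5 (0.60 ± 0.16) rose too. Pcsk1n, an inhibitor gene of a prohormone convertase, fell from 43.8 ± 5.29 to 29.9 ± 3.71 FPKM (-0.54 ± 0.14), and smaller falls were those of Arxes1 (-0.26 ± 0.06), Ly6h (-0.25 ± 0.06), Tmem158 (-0.24 ± 0.05), Fam3c (-0.20 ± 0.05) and Olfm1 (-0.18 ± 0.05). By number of introns, the median log2 change in cytosol was 0.152 over 2584 coding genes with more than 15 introns, 0.110 over 3144 with 9 to 15, 0.0663 over 3659 with 4 to 8, 0.0531 over 1648 with 1 to 3 and 0.0344 over 145 with 0. With medians taken within each culture, the class with more than 15 introns lay above that with 0 by 0.127 ± 0.0305 (mean and SD over 3 cultures). The same difference was -0.0731 ± 0.0744 in nuclei and -0.00359 ± 0.0326 in whole cells, where the medians of the fitted changes were 0.0588 and 0.0475. Of 20 immediate early genes 5 rose (11 adjusted over the list alone, 17 with replicate number as a block), among them Cyr61 (0.95), Fosb (0.90) and Per1 (0.79), with a list median of 0.46 (camera adjusted p = 3.24e-07, and adjusted p = 0.461 with an estimated correlation, which became 0.0158 with the block). Of 38 CLK and SR genes 2 rose (10 adjusted over the list alone), Pnisr and Srrm3 (0.30). That list had an adjusted p = 0.461 with an estimated correlation, after 9.98e-04 with the preset one. Of 53 voltage-gated channels 4 rose, among them Cacnb4 (0.43), Cacna1d (0.41) and Kcnh7 (0.38), with a list median of 0.09 (-0.00 with median-ratio scaling), adjusted p = 0.788 and adjusted p = 0.893 with an estimated correlation.

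Over all genes the median log2 change in cytosol was 0.0840, and other lists lay lower than that rise. They were the glutamatergic synapse genes (median 0.00, with 3 of 48 called higher, among them Dlg1 at 0.34 and Dlgap2 at 0.30), GABAergic synapse genes (0.02), astrocyte markers (0.01), ribosomal protein genes (0.01), mitochondrially encoded RNAs (-0.22), oxidative phosphorylation genes (-0.02) and genes hosting small nucleolar RNAs (-0.02). The list test is relative to all genes, so it was negative for the first 4 lists although their medians were above 0. The astrocyte mean was -0.00, and the mean of the small nucleolar RNA hosts was 0.01 against a median of -0.02. With median-ratio scaling those 4 medians were -0.08, -0.08, -0.08 and -0.08. The mitochondrially encoded median was -0.31 with median-ratio scaling and 0.00 with quantile normalization. Each had an adjusted p of 0.461 to 0.635 with an estimated correlation. Npas4 (0.84), Fos (0.67), Arc (0.64), Egr1 (0.48), Nr4a1 (0.41) and Clk4 (0.45) passed the test with replicate number as a block (adjusted p = 4.21e-05, 1.34e-05, 5.16e-04, 5.16e-04, 0.00277 and 0.0299) and not without it. Clk1 (0.46), Bdnf (-0.16) and Meg3 (0.23) passed neither. Across the transcriptome limma called 465 of 14205 genes, 452 higher and 13 lower, at 2769 genes with an unadjusted p under 0.05. The excess of rises depended on the scaling, since 30 genes were called with median-ratio scaling, 20 higher and 10 lower. With the block 2175 were called (2062 higher, 113 lower), and 1028 (541 higher, 487 lower) with the block and median-ratio scaling. Without bicuculline cytosol 1, 2 or 3 the counts were 106, 117 and 15, and without unstimulated cytosol 1 or 3 they were 45 and 12. Of 25 named calls that of Per1 held in each such fit, and 21, 19, 24, 21, 12 and 23 were lost without bicuculline 1, 2 and 3 and unstimulated 1, 2 and 3. With only the 6 cytosolic libraries in the fit 10 genes were called. Bicuculline cytosols lay at 0.0909 ± 0.0459 on the scale from cytosol to nuclei and unstimulated ones at 0.0141 ± 0.0144 (SD, n = 3 each, 2-sided exact permutation test p = 0.1, the smallest possible). This test, like that of the nuclei, took the libraries as unpaired. By culture the bicuculline and unstimulated cytosols lay at 0.144 and 0.0287, 0.0690 and 0.0136, and 0.0601 and 5.7e-05. The cytosolic and nuclear responses correlated at r = 0.0788 across genes, and 27 genes were called in the same direction in both, against 4.56 if independent.

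**Figure D4:**
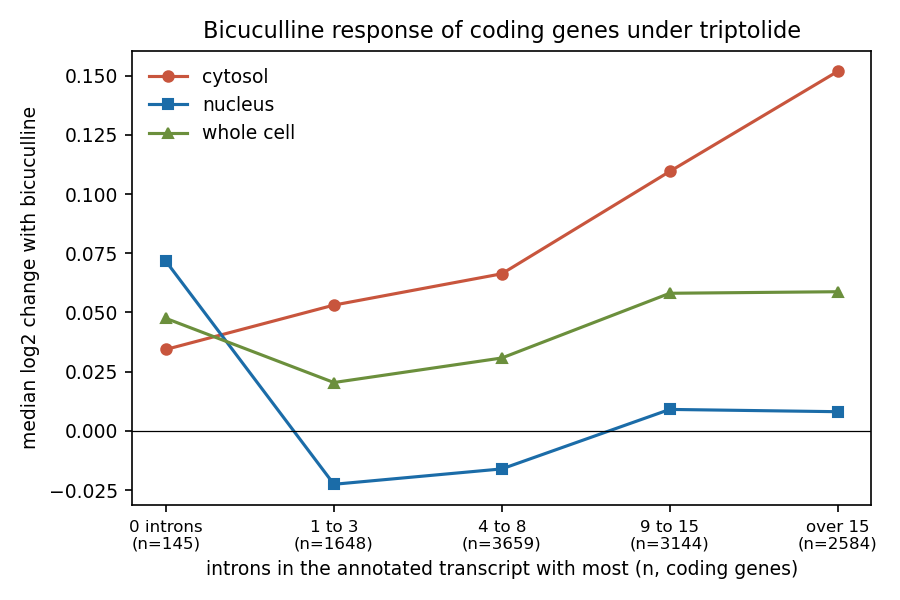
Median log2 change with bicuculline under triptolide (vertical axis) of coding genes grouped by the number of introns of their annotated transcript with most introns (horizontal axis), in cytosol (circles), nuclei (squares) and whole cells (triangles). The cytosolic median runs from 0.0344 with 0 introns to 0.152 with more than 15, and 0.690% and 8.24% of these genes were called higher in cytosol.

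The nuclear and cytosolic responses to bicuculline were compared directly, as an interaction. The response of Reln was larger in nuclei by 0.76 ± 0.10 (adjusted p = 0.00416), being 0.68 there. Lrp12 (0.48 ± 0.09), the adhesion protein genes Clstn3 (0.42 ± 0.09) and Cdh8 (0.40 ± 0.08), Sez6l2 (0.42 ± 0.08) and Arxes1 (0.40 ± 0.08) had a more positive response in nuclei as well. Gigyf1 (-1.36 ± 0.23), Zscan26 (-0.97 ± 0.12), the splicing factor gene Sart3 (-0.95 ± 0.14), Med23 (-0.85 ± 0.12), a gene of the Mediator complex, Ppp1r12c (-0.85 ± 0.13) and Gtf2ird1 (-0.84 ± 0.11) had a more positive response in cytosol. Glutamatergic synapse genes lay higher in this comparison (median 0.16, camera adjusted p = 1.28e-10, and adjusted p = 0.0154 with an estimated correlation, which became 0.0578 with replicate number as a block). Of the 48, limma called 0 over all genes, with 12 higher and 4 lower at an unadjusted p under 0.05, and adjusted over the list alone 10 were higher and 2 lower. GABAergic synapse genes (median 0.15), voltage-gated channels (0.06) and delayed activity genes (0.12) lay higher and CLK and SR genes (-0.28) and ribosomal protein genes (-0.24) lower, with adjusted p = 0.0704, 0.0855, 0.635, 0.635 and 0.642 with an estimated correlation. Npas4 (-0.73), Clk4 (-0.69) and Bdnf (0.45) passed the test with the block (adjusted p = 0.00249, 0.0340 and 0.0421) and not without it. Fos (0.07), Arc (0.06), Egr1 (-0.10), Nr4a1 (-0.29), Clk1 (-0.68) and Meg3 (-0.25) passed neither. Over all genes limma called 79 of 14205 genes, 12 more positive in nuclei and 67 in cytosol, at 2326 genes with an unadjusted p under 0.05. The median over all genes was -0.114, and with median-ratio scaling, where it was -0.0342 (-0.00397 with quantile normalization), 132 genes were called, 86 more positive in nuclei and 46 in cytosol. With the block 1387 were called (404 and 983), and 1095 (745 and 350) with the block and median-ratio scaling. Without nuclear libraries bicuculline 1, 2, 3 and unstimulated 1 and 3 the counts were 18, 671, 17, 15 and 12, and without cytosolic libraries bicuculline 1, 2, 3 and unstimulated 1, 2 and 3 they were 9, 36, 26, 46, 37 and 15. The calls of Reln, Zscan26, Sart3, Med23, Ppp1r12c and Gtf2ird1 held in each of these fits, and the other 6 named calls did not. Without bicuculline nuclei 1 and 3 together 1 gene was called. Of the exonic length of Zscan26, 23.6% overlaps a gene on the opposite strand.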

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

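The tests of carry-over between fractions, of membrane-bound mRNA in the nuclear pellet and of scaling, and the gene families used for membrane and soluble proteins with each test on them, were chosen only after the results were seen. The tests of transcript length for ribosomal protein genes and of gene span and the counts of other splits were planned before. In each comparison of 3 against 3 libraries 1 of the 10 splits, the real one, gave as many called genes, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 41 and 0 for bicuculline under DRB, 85 and 0 for BDNF, 17 and 0 for BDNF against bicuculline, 5 and 0 for whole cells, 257 and 0 for nuclei, 465 and 0 for cytosol, 9511 and 0 for nucleus against cytosol in unstimulated cells, and 8983 and 1 after bicuculline. Like the real split, 3 of the other splits part all 3 same-numbered pairs, and they gave at most 0 genes, or 1 for nucleus against cytosol after bicuculline.

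The nuclear and cytosolic responses to bicuculline differed by a test of the difference itself, for 79 genes. Among the named ones the difference was 0.76 for Reln, 0.48 for Lrp12, 0.42 for Clstn3, 0.42 for Sez6l2, 0.40 for Arxes1 and 0.40 for Cdh8, and -1.36 for Gigyf1, -0.97 for Zscan26, -0.95 for Sart3, -0.85 for Med23, -0.85 for Ppp1r12c and -0.84 for Gtf2ird1. Over the glutamatergic synapse genes the median difference was 0.16 (adjusted p = 0.0154 with an estimated correlation, which became 0.0578 with replicate number as a block). Carry-over between the fractions was not tested for this list. Of 100 drawn splits of the 12 libraries 3, the real one included, called as many genes. This share is under the limit of 0.05 set beforehand, but the draws take the libraries as unpaired, so it does not exclude chance. The highest of the others called 697 genes, and a split that broke up the nuclear groups called 258, several times the real 79, which points to a structure of the samples that the groups do not describe, and the count of 79 ranged from 9 to 671 when 1 library was left out.

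The bicuculline responses under DRB and in whole cells under triptolide also differed by a test of the difference, for 19 genes. The difference was 4.12 for Npas4, 3.72 for Arc, 3.0 for Fosb, 2.89 for Fos, 2.52 for Gadd45g and 1.85 for Egr4, and the median over the immediate early genes was 1.24 (adjusted p = 0.00183 with an estimated correlation). Of 100 drawn splits 5 called as many genes, the real one included, so chance cannot be excluded by this count, and the highest of the others called 41. The 4 other splits with as many genes all kept the groups under DRB as they were, and the highest count of a split that broke them up was 2. Inhibitor, duration and cultures differ together between the experiments, and no biological explanation of the difference was tested. The RNA fraction of the DRB libraries is not stated in their titles, while the triptolide libraries compared are of whole cell extract.

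In nuclei after bicuculline, ribosomal protein mRNAs lay lower (9 of 76 called, adjusted p = 0.195 for the list with an estimated correlation). Cytosol carried over into the bicuculline nuclei is argued against as the cause, since these mRNAs had nearly equal nuclear and cytosolic levels and lay at -0.247 ± 0.0978 (SD over 3 cultures). Their median log2 ratio was -0.0205, or -0.0946 with median-ratio scaling and 0.116 with quantile normalization. Relative to the 20 coding genes nearest in length of the longest annotated transcript they lay at -0.140 ± 0.0550. This argues against transcript length as the whole cause, and a part of the fall may go with it. Membrane and secreted protein families, picked by symbol, differed from the 20 nearest soluble-family genes by 0.0563 ± 0.0311 when matched on the ratio of nucleus to cytosol in the other cultures and by 0.0877 ± 0.0450 when matched on length. Both lie less than 2 SD over cultures above 0, the limit used here, while the ribosomal tests used a different limit of fewer SD. In cultures 1, 2 and 3 the values were 0.0319, 0.0457 and 0.0913 matched on the ratio. Matched on length they were 0.109, 0.0359 and 0.118. By this limit no rise of these families beyond carry-over or length is shown, and none is excluded. A move of their mRNA from cytosol to the nuclear pellet (-0.0892 ± 0.117 in cytosol) stays open. A bicuculline effect on nuclear mRNA remains open beside these, and the dependence of the 257 calls on single libraries applies to it.

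In cytosol after bicuculline, genes with more than 15 introns lay above genes with none by 0.127 ± 0.0305 (SD over 3 cultures), against -0.0731 ± 0.0744 in nuclei and -0.00359 ± 0.0326 in whole cells. With quantile normalization this difference was 0.126 ± 0.0301. A factor shared by all genes of a library largely cancels in a difference between medians, so this value is no test of such scaling. The number of called genes went from 465 to 30 with median-ratio scaling and 2 with quantile normalization, so for that number scaling stays open. Nuclear RNA carried over into the cytosol stays open. Genes with more than 15 introns exceeded the 20 genes with 3 or fewer introns nearest in the ratio of nucleus to cytosol by 0.0864 ± 0.0460. This is less than 2 SD over cultures above 0, with 0.0663, 0.0540 and 0.139 in cultures 1, 2 and 3. Going with carry-over, genes with a log2 ratio over 1 in the other cultures lay above those under 0 by 0.102 ± 0.0832 in cytosol. In nuclei that difference was -0.213 ± 0.288 and in whole cells -0.148 ± 0.162. The bicuculline cytosols, too, lay nearer the nuclei than the unstimulated ones (0.0909 and 0.0141). A bicuculline effect on cytosolic mRNA stays open beside carry-over, and how it would act was not tested.

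Under DRB, an inhibitor of elongation, 20 of 27 immediate early genes rose. How much transcription was left under DRB was not measured. Each culture gave 1 library to each group, so the design balances differences between cultures. A candidate explanation is transcription of short genes escaping DRB, which may account for the rise: 39 called genes with a known span had a median span of 5799 bases against 27567 in expression-matched lists, which is percentile 0 among 10000 such lists. Immediate early genes are short in general, so this does not set escape from DRB apart from other explanations that involve the same genes, and a longer life of their mRNAs stays open and untested. The difference from triptolide, which acts on initiation, cannot decide either, since the experiments also differ in duration and cultures.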

How the results depend on the processing

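The fits with the replicate block together with median-ratio scaling and those without bicuculline nuclei 1 and 3 were chosen only after the results were seen. Among the values of single named genes under all alternatives, 4573 kept direction and side of the threshold, 671 kept direction and no longer passed, 60 newly passed and 58 changed direction, and of the counts of called genes and lists 210 stayed within 1.5 times and 105 did not. Except where fewer genes or samples explain a lower count, the cause was not tested. At a mean FPKM of at least 5, with fewer genes tested, the calls were 26 for bicuculline and 44 for BDNF under DRB, 0 for whole cells under triptolide (limma, with 983 genes at an unadjusted p under 0.05), 5567 for nucleus against cytosol, unstimulated, 5469 for nucleus against cytosol, bicuculline, and 7 for DRB against triptolide. Without a filter they were 561 in nuclei, 106 in cytosol, 29 for nuclear against cytosolic response, 19387 for nucleus against cytosol, unstimulated, and 16850 for nucleus against cytosol, bicuculline. Median-ratio scaling gave 30 in cytosol and 132 for nuclear against cytosolic response, and quantile normalization 437 in nuclei, 2 in cytosol and 33 for the difference. Variance moderation without trend gave 27 for BDNF against bicuculline and 10 for whole cells. With only the groups compared in the fit, and so fewer samples behind the spread, the counts were 6 for BDNF against bicuculline, 3 for whole cells, 1 in nuclei, 10 in cytosol and 5 for the difference. A pseudocount of 1 FPKM gave 3 for whole cells, and one of 0.1 FPKM 11 for DRB against triptolide. The replicate block gave 76, 199, 72, 601, 1862, 2175, 1387 and 38 calls for bicuculline and BDNF under DRB, BDNF against bicuculline, whole cells, nuclei, cytosol, nuclear against cytosolic response and DRB against triptolide, and 59 genes shared by both stimuli under DRB. With median-ratio scaling added these were 69, 181, 72, 330, 2032, 1028, 1095, 40 and 58. Without bicuculline nuclei 1 and 3 the nuclear count was 14 and that of the difference 1. Over all 20 lists, camera with the preset correlation passed 7, 6, 5, 8, 11, 10, 6, 6, 6 and 10 lists for bicuculline and BDNF under DRB, BDNF against bicuculline, whole cells, nuclei, cytosol, nuclear against cytosolic response, nucleus against cytosol in unstimulated and bicuculline cells, and DRB against triptolide. With an estimated correlation it passed 2, 2, 0, 0, 1, 0, 1, 0, 0 and 1. By fry, which does not compare a list with other genes, 2, 3, 0, 0, 5, 6, 0 and 10 lists passed in the first 8 of these, and 1 for DRB against triptolide. With the replicate block camera gained 16 lists and lost 2 with the preset correlation, and gained 3 and lost 4 with the estimated one. Of the 16 gained, only the glutamatergic synapse list of unstimulated cells is named with the results. The block changed no other call of a named gene than those given with the results.

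With 1 library left out, where the lone or smaller group is assumed to vary like the others, the calls ranged from 27 to 35 for bicuculline and 52 to 69 for BDNF under DRB, 9 to 20 for BDNF against bicuculline, 1 to 5 in whole cells, 21 to 524 in nuclei, 12 to 334 in cytosol, 9 to 671 for nuclear against cytosolic response, 8836 to 9192 and 7949 to 8679 for nucleus against cytosol in unstimulated and bicuculline cells, and 12 to 19 for DRB against triptolide, and the genes shared by both stimuli from 24 to 31. The lists ranged from 6 to 11, 6 to 10, 3 to 7, 6 to 13, 7 to 12, 8 to 12, 6 to 7, 5 to 7, 5 to 7 and 7 to 14 in the same order of comparisons. The lowest or highest list counts that differed by over 1.5 times came without DRB bicuculline 2 (11 lists) for bicuculline, without DRB unstimulated 2 (10) for BDNF, without DRB bicuculline 3 (3) for BDNF against bicuculline, without whole unstimulated 1 (13) and without nuclear bicuculline 2 (7). Named genes that changed direction had not been called, except Pdgfrb. Their ranges were -0.029 to 0.074 for Clk4 and -0.74 to 0.0030 for Meg3 with bicuculline under DRB, -0.37 to 0.24 for Meg3 with BDNF, and -0.33 to 0.0086 for Bdnf, -0.021 to 0.21 for Nr4a1 and -0.069 to 0.68 for Meg3 between the stimuli. In whole cells they were -0.049 to 0.22 for Bdnf, -0.36 to 0.028 for Meg3 and -0.29 to 0.061 for Clk1, in nuclei -0.37 to 0.16 for Meg3, -0.068 to 0.31 for Npas4 and -0.080 to 0.25 for Nr4a1, and in cytosol -0.27 to 0.027 for Bdnf. For nuclear against cytosolic response they were -0.10 to 0.22 for Fos, -0.29 to 0.11 for Egr1 and -0.26 to 0.33 for Arc, for nucleus against cytosol -0.25 to 0.14 for Egr1 in unstimulated and -0.33 to 0.028 in bicuculline cells, and for DRB against triptolide -0.58 to 0.16 for Meg3. Without bicuculline nuclei 1 and 3 the nuclear changes of Clk1 (0.13), Clk4 (0.040), Nr4a1 (-0.13), Npas4 (-0.31), Bdnf (-0.034) and Meg3 (0.67) changed direction, as did the differences of Fos (-0.24), Arc (-0.49) and Meg3 (0.44) and the bicuculline fraction ratios of Nr4a1 (-0.091), Arc (-0.19) and Npas4 (-0.15). With quantile normalization these were Egr1 (0.065) for the difference, Pdgfrb (-0.087) and Arc (-0.30) for the unstimulated fraction ratio, and Pdgfrb (-0.061), Nr4a1 (-0.0099) and Npas4 (-0.089) for that after bicuculline. Depth limits little here, since 10 fragments on 2 kb make an FPKM of 0.0338 to 0.0739 and tested genes reached 1 in 3 libraries.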

Other observations

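The lists with some of the larger median differences between replicate numbers are given here as values. They were looked at only after the data were seen, and none was tested. Each value is the median log2 difference of a list between the libraries of one number and the other libraries of the experiment. Under triptolide, 9 microglia markers lay at 1.25 in culture 1 (8 members positive), at -1.48 in culture 2 (1 positive) and at 0.32 in culture 3 (9 positive), and immediate early genes lay at -0.27 in culture 2 and 0.26 in culture 3. Oligodendrocyte markers lay at 0.33 in culture 2 (10 of 12 positive). Under DRB, whose cultures are other ones, culture 2 had progenitor and proliferation genes at -0.60 (3 of 16 positive), nuclear long noncoding RNAs at 0.65 (11 of 13), oligodendrocyte markers at 0.42 (10 of 13) and voltage-gated channels at 0.22 (49 of 54). Culture 3 had oligodendrocyte markers at -0.74 (2 of 13 positive) and culture 1 progenitor genes at 0.33 (14 of 16).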
